A study of Homo sapiens and Mus musculus with 8 samples.

How the data were processed

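RNA was sequenced from 8 libraries: in the human small cell lung cancer line H146 and the mouse small cell lung cancer line F1339, 2 vehicle and 2 decitabine (0.5 µM) libraries each, at 96 h in H146 and 72 h in F1339. Libraries were grouped by line and treatment as their labels give them, and replicate numbers 1 and 2 were kept. The labels call the libraries of an arm duplicates and do not say whether these are separate cultures.

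The deposited tables hold 1 signal value per gene and library, which are gene counts that the authors divided by 1 size factor per library (normalized counts, not logged). The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and DESeq2, and the build GRCh38 also for the mouse samples. The mouse build, the annotation and the strandedness are not given in the sources used here. Whole reads could be recovered: 100% of the values of each library are whole multiples of its value of 1 read, within 0.001 read, and that value lies between 0.960 and 1.08 across the libraries. The tables hold 20863 genes for H146 and 16833 for F1339, and the lowest total of reads of a listed gene is 41 in each, so genes under some such total were removed before deposit.

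The authors' deposited tables also give a log2 fold change, a p-value and an adjusted p-value per gene. From the values themselves, the sign of the authors' fold change in H146 is that of vehicle over decitabine for 4854 of the 4854 genes called there, and in F1339 it is that of decitabine over vehicle for 107 of 107. All fold changes given here run from vehicle to decitabine. In H146, 24 gene symbols had been turned into dates and were restored from their Ensembl IDs, and 73 were blank. In F1339, 23 had been turned into dates and were not restored, since no mouse annotation was used here, and 28 were blank. Positions and gene types of H146 genes come from GENCODE release 29 matched by Ensembl ID (20757 of 20863 IDs). No per-sample column of the tables was left out.

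Recovered reads per library are 67108249 and 62462654 in vehicle and 66740982 and 66454903 in decitabine for H146, and 61364041 and 67892360 in vehicle and 63816317 and 63917063 in decitabine for F1339. At this depth 1 read is about 1 normalized count, so genes with a few counts carry a large counting error, and folds are given with an interval for them. Mitochondrially encoded genes take 6.09% to 7.56% of reads in H146 and 1.22% to 1.82% in F1339, and the 10 most abundant genes of a library take 4.74% to 8.34%.

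Normalized counts were put on the log2 scale with a pseudocount of 1, and genes with at least 10 in at least 2 of the 4 libraries of a line were tested, 20783 in H146 and 16680 in F1339. Each line was fitted on its own with limma 3.58.1 (treatment as the only term, eBayes with a variance trend), and p values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Counts of genes changed 2-fold or more add a limit on the fitted fold. Folds in the text are ratios of mean normalized counts. Where an arm had no reads the fold is a lower bound against 3 reads over the arm, and with 1 to 3 reads it is a ratio with a 95% counting interval.

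The 22 gene lists were written before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes. They were tested per line with camera at a preset correlation of 0.01, adjusted over the lists of a line, then with an estimated correlation per list and with fry. Lists with fewer than 5 tested members were left out. The named genes are a fixed set of 14 (among them DNMT1, RB1, NEUROD1, INSM1, POU2F3, YAP1, MYC, MYCL, MYCN, CDKN1A, CDKN1B, MKI67), the 8 highest and 8 lowest called protein-coding genes of each line with a mean of at least 50 and separated arms, up to 3 called members per list or else the 2 most abundant, and genes called in both lines. POU2F3 was not among the tested H146 genes. Some genes that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen. Genes tested in both lines were matched by one-to-one symbol, and the overlap of calls was tested with the hypergeometric distribution.

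Alternatives changed 1 choice at a time: pseudocounts of 5 and 0.5, no filter, a filter of at least 50, rescaling to the same upper quartile or the same total, eBayes without a variance trend, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and each library left out in turn. With 1 library left in an arm, that library is assumed to vary like the other arm. The procedure was tested on simulated data with the depth and spread of each line. In the H146 simulation limma called 76.1%, 85.1% and 100% of genes changed 1.5-, 2- and 4-fold, and in the F1339 simulation 0%, 20.9% and 66.7%, where DESeq2 called 5.97%, 37.3% and 87.9%. Of unchanged genes limma called 0.0196% in the H146 and 0.0183% in the F1339 simulation, and DESeq2 0.0343% and 0.169%. Lists of 30 members moved 1.5-fold were called in the simulations of H146 and F1339 by camera, with the preset and the estimated correlation (p = 0.0042 and 0.0093), and by fry. Genes were simulated independently of one another, without any shared spread of list members. The simulation therefore does not show how readily the list tests call such lists in the real libraries. Libraries were also simulated independently, without a spread shared by libraries of the same number. The shares of genes called in the F1339 simulation therefore need not hold for the real F1339 libraries. The programs were R 4.3.3, python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.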

Results

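Small cell lung cancer cells are neuroendocrine, and decitabine is a deoxycytidine analog that, once built into DNA, traps and depletes the maintenance DNA methyltransferase DNMT1. The RNA-seq data address which genes cells of this cancer turn on or off when DNMT1 is depleted, and whether these are genes of cell cycle exit and maturation or of the p53 pathway and cell death. There are 8 libraries, from the human line H146 and from the mouse line F1339. In each line 2 libraries come from vehicle-treated cells and 2 from cells given 0.5 µM decitabine, sampled at 96 h for H146 and at 72 h for F1339. The libraries hold 62462654 to 67108249 gene-assigned reads each in H146 and 61364041 to 67892360 in F1339. Values are normalized counts, given as mean ± SD (n = 2 per arm), and adjusted p values are Benjamini-Hochberg values from limma over all genes tested in a line. Lists of genes fixed in advance were tested with camera, and beside each list call stands the adjusted p with an estimated correlation, with which no list was called in either line.

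In H146, 17 of the 23 germline genes tested rose, some of them from near silence. The list holds 30 genes. A gene under 10 in both vehicle libraries is tested only if both decitabine libraries reach 10. The share is thus of detected genes and leans toward rises. DAZL, an RNA-binding protein of germ cells, went from 0.502 ± 0.709 in vehicle to 446 ± 12.9 in decitabine (n = 2 per arm), a ratio of 889 (95% counting interval 157 to 34739; adjusted p 6.7e-14). The testis transcription factor gene DMRTB1 reached 478 ± 33.2 from 1 ± 1.42 (ratio 476, interval 129.8 to 3889). BRDT, a testis bromodomain gene, reached 225 ± 10.5 from no reads, which is at least 148-fold higher with a floor of 3 reads over the arm. These intervals cover counting error only, not the spread between cultures. SYCP3 of the meiotic chromosome axis rose 83.8-fold to 766 ± 23 and MAEL, a piRNA pathway gene, rose 18.8-fold to 1009 ± 17.1. The piRNA pathway genes PIWIL2 (9.14 ± 1.58 to 239 ± 9.31) and TDRD1 (20.3 ± 3.20 to 267 ± 0.436) rose too, while TEX15 stood at 546 ± 29.1 and 508 ± 126 and was not called. SYCP3, MAEL, PIWIL2, TDRD1 and TEX15 were chosen after their values were seen. Of 23 tested germline genes 17 were higher and 0 lower, also when adjusted over the list alone. Their median log2 fold change was 3.66 (camera adjusted p 6.9e-19; adjusted p = 0.209 with an estimated correlation). The median is also 3.66 with the gene that had no reads set at its bound.

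Part of the X-linked cancer-testis antigens rose in H146. VCX, which is normally expressed in male germ cells, went from 14.3 ± 5.97 to 3446 ± 369 (n = 2 per arm; 242-fold, limma adjusted p 1.5e-19), and VCX2 rose 339-fold and VCX3A 236-fold. These 3 genes are close paralogs whose reads can be assigned to one another. CTAG2 rose from 71.4 ± 13.9 to 812 ± 174 and PAGE2B from 379 ± 30.4 to 2172 ± 198. MAGEA3 (15051 ± 1088 and 15281 ± 427) and MAGEC2 (20886 ± 1598 and 21912 ± 227) were already abundant in vehicle and were not called. CTAG2, PAGE2B, MAGEA3 and MAGEC2 were chosen after their values were seen. Of the 40 listed members 26 were tested, of which 10 were higher and 0 lower, and the same counts hold when adjusted over the list alone. The median was 0.29 (camera adjusted p 6.2e-07; adjusted p = 0.452 with an estimated correlation).

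Of the imprinted genes tested 10 rose. NNAT, a paternally expressed gene of neurons, went from 216 ± 9.26 to 21121 ± 2176 (n = 2 per arm; 97.7-fold, adjusted p 3.5e-24), RTL1 from 0.502 ± 0.709 to 29.4 ± 3.45 (ratio 58.7, interval 10.0 to 2333) and H19 from 5.62 ± 5.11 to 28.7 ± 16.0. The paternally expressed genes DLK1 (10704 ± 1240 to 19922 ± 3125) and MEST (12483 ± 607 to 20433 ± 63.5), chosen after their values were seen, rose less. Of 21 imprinted genes 10 were higher and 0 lower, 12 and 0 when adjusted over the list alone. The list median was 0.49 (camera adjusted p 9.6e-07; adjusted p = 0.252 with an estimated correlation). H19 loses its call without decitabine replicate 1 (adjusted p 0.196) and in limma without a variance trend (0.137).

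Part of the cell cycle exit genes and of the p53 targets rose in H146. BTG2, an antiproliferative p53 target, rose from 889.6 ± 19.9 to 3051 ± 1.41 (n = 2 per arm; log2 fold change 1.78 ± 0.11 SE, adjusted p 1.6e-12), and the polo-like kinase gene PLK2 from 2401 ± 53.4 to 7909 ± 1.18 (1.72). The CDK inhibitor genes CDKN1C and CDKN1A rose from 409 ± 20.3 to 1099 ± 139 (1.42) and from 6023 ± 512 to 9292 ± 260.4 (0.63, adjusted p 3.4e-05). CDKN1A loses its call in limma without a variance trend (adjusted p 0.0535). CDKN1B, the p27 gene, stood at 9093 ± 458 and 9273 ± 198 and was not called. Of 21 cell cycle exit genes 9 were higher and 0 lower, 9 and 1 when adjusted over the list alone. Their median was 0.26 (camera adjusted p 0.00074; adjusted p = 0.252 with an estimated correlation). Of 26 p53 targets 16 were higher and 2 lower, 16 and 3 when adjusted over the list alone. The p53 list had a median of 0.42 (camera adjusted p 2.2e-06; adjusted p = 0.252 with an estimated correlation). Beside BTG2 the largest rises among them were SPATA18 (165 ± 1.61 to 779.9 ± 31.0) and GDF15 (593 ± 59.9 to 1812 ± 288). PLK3 (−0.63) and TRIAP1 (−0.31), chosen after their values were seen, fell. The p53 target MDM2 (6899 ± 226 and 6625 ± 209), chosen after its values were seen, was not called.

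Among apoptosis regulators the BH3-only genes BMF (512 ± 17.5 to 1228 ± 47.9; log2 fold change 1.26) and BBC3 (765 ± 47.6 to 1338 ± 87.5; 0.81) rose, and the survival gene BCL2L1 fell from 9472 ± 554 to 6659 ± 436 (−0.51 ± 0.10 SE, n = 2 per arm). BCL2L1 loses its call in limma without a variance trend (adjusted p 0.0779). Of 28 such genes 6 were higher and 3 lower, the same when adjusted over the list alone. With a median of 0.07 the list was not called (camera adjusted p 0.417). Proliferation genes went both ways: the licensing factor CDT1 rose from 5405 ± 111 to 8942 ± 777 and the mitotic transcription factor FOXM1 from 16031 ± 633 to 23117 ± 23.2. The cyclin E gene CCNE1 fell from 1547 ± 179 to 877 ± 37.7 (−0.81), and MKI67 (27191 ± 1605 and 28696 ± 5461) was not called. FOXM1 loses its call in limma without a variance trend (adjusted p 0.0582). Of 35 proliferation genes 10 were higher and 5 lower, 11 and 5 when adjusted over the list alone. This list, with a median of 0.14, was not called (camera adjusted p 0.110), but it is called, upward, with libraries rescaled to the same total (0.0309). RB1 fell from 514 ± 50.7 to 388 ± 67.7 (−0.41, adjusted p 0.045). That call is lost without vehicle replicate 2 (0.175), decitabine replicate 1 (0.467) or decitabine replicate 2 (0.0747), with DESeq2 (0.102), with libraries rescaled to the same total (0.102) or upper quartile (0.0664), and in limma without a variance trend (0.211).

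MYC and most of the tested genes of its list fell in H146. MYC went from 10514 ± 1341 to 6038 ± 114 (n = 2 per arm; log2 fold change −0.79 ± 0.10 SE, adjusted p 2.2e-06), and the ribosome biogenesis genes UTP20 from 3103 ± 248 to 1409 ± 199.8 (−1.14) and NOP16 from 1569 ± 119.5 to 959.9 ± 96.4 (−0.71). NOP16 loses its call in limma without a variance trend (adjusted p 0.0535). The nucleolin gene NCL, chosen after its values were seen, fell from 58279 ± 1729 to 41714 ± 1827 (−0.48). Of 30 list members 23 were lower and 0 higher, 25 and 0 when adjusted over the list alone. The median of the MYC list was −0.46 (camera adjusted p 3.1e-11; adjusted p = 0.259 with an estimated correlation). The paralogs MYCL (223 ± 6.41 and 205 ± 23.8) and MYCN (73.7 ± 14.8 and 100.4 ± 10.8) were not called.

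Lineage genes moved in both directions. The neurogenic factor gene NEUROD1 rose from 29.9 ± 1.66 to 247 ± 63.0 (n = 2 per arm; log2 fold change 2.98 ± 0.26 SE, adjusted p 1.8e-09). INSM1 was at 51227 ± 2943 and 54559 ± 3120, with no call. Of 15 neuroendocrine transcription factors 5 were higher (NEUROD1, NKX2-1, and FOXA2, SOX2 and SOX11, the last 3 chosen after their values were seen) and 1 was lower, the same counts when adjusted over the list alone. The list was not called, with a median of 0.12 (camera adjusted p 0.110). NKX2-1 loses its call without vehicle replicate 1 (adjusted p 0.203), decitabine replicate 1 (0.19) or decitabine replicate 2 (0.319), with DESeq2 (0.139), with libraries rescaled to the same total (0.0696), and in limma without a variance trend (0.133). Among the neuroendocrine and neuronal effectors the peptide gene GRP rose from 332 ± 26.9 to 1151 ± 190.0 (1.78). SCG5 rose from 60.8 ± 10.5 to 156 ± 42 (1.33). The chromogranin A gene CHGA fell from 19497 ± 1674 to 12077 ± 831 (−0.69). SCG5 loses its call without decitabine replicate 1 (0.0893), and CHGA (0.0508) and SCG5 (0.0516) lose theirs in limma without a variance trend. Of 36 effectors 11 were higher and 4 lower, 12 and 4 when adjusted over the list alone. With a median of 0.12 they were not called as a list (camera adjusted p 0.0637, and 0.05, just under the threshold, without decitabine replicate 2). With libraries rescaled to the same total that list is called (0.0406).

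Of 24 genes of the non-neuroendocrine state and the Notch pathway in H146, 7 were higher and 1 lower, also when adjusted over the list alone. With a median of 0.16 the list was not called (camera adjusted p 0.0507), but it is called without vehicle replicate 1 (0.0369) or decitabine replicate 1 (0.0275) and with a pseudocount of 5 (0.0456). The Notch effector gene HES1 rose from 76.3 ± 29.9 to 194 ± 23.5 (n = 2 per arm), LGALS1 from 134 ± 18.7 to 346 ± 34.8 and ANXA2 from 6522 ± 5.65 to 14094 ± 1103, while the receptor gene NOTCH3, chosen after its values were seen, fell from 331 ± 38.4 to 206 ± 1.54. HES1 loses its call without decitabine replicate 1 (adjusted p 0.0642) and in limma without a variance trend (0.0726). YAP1 (37.5 ± 6.56 and 29 ± 0.0115) was not called. Among 5 tuft cell genes 1 was higher and 1 lower, ASCL2 (138 ± 37.4 to 40.1 ± 15.7), the same when adjusted over the list alone. This list was not called (camera adjusted p 0.999), with a median of 0.19, a mean of −0.11 and a downward test direction. ASCL2 loses its call in limma without a variance trend (0.0584). Markers of other cell types also moved. Of 10 endothelial and lung epithelial markers 7 were higher and 0 lower, the same when adjusted over the list alone, led by PECAM1 (59.6 ± 24.6 to 418 ± 7.19). Their median was 0.95 (camera adjusted p 3.7e-05; adjusted p = 0.252 with an estimated correlation). Of 12 fibroblast markers 7 were higher and 1 lower, the same when adjusted over the list alone. FN1 rose from 1437 ± 214 to 3086 ± 317 and COL1A2 from 261 ± 39.5 to 525 ± 10.7, and the fibroblast list had a median of 0.60 (camera adjusted p 0.0143; adjusted p = 0.418 with an estimated correlation; 0.122 without vehicle replicate 2, which ends the call). Of 11 immune cell markers 2 were higher, among them FCER1G (9.17 ± 4.45 to 89.0 ± 2.86), and PTPRC (419.5 ± 1.06 to 301 ± 22.5) was lower, the same when adjusted over the list alone. The immune list was not called, with a median of 0.32 (camera adjusted p 0.217). PTPRC loses its call without decitabine replicate 1 (0.218) or 2 (0.0977) and in limma without a variance trend (0.0806).

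The remaining H146 lists were not called by camera. Of 35 interferon response genes 7 were higher and 1 lower, also when adjusted over the list alone, with a median of 0.28 (camera adjusted p 0.0607). The interferon list is called with libraries rescaled to the same total (0.0481). The antiviral gene MX2 rose from 33.6 ± 12 to 213 ± 36.5 (n = 2 per arm) and IRF1 from 405 ± 27.1 to 742 ± 87.6, while EIF2AK2, chosen after its values were seen, fell from 3968 ± 222 to 2567 ± 126. Of 21 antigen presentation genes 5 rose, also when adjusted over the list alone, and 0 fell (median 0.16, camera adjusted p 0.115). Among them are CD74 (252 ± 19.2 to 524 ± 35.9), HLA-B (3421 ± 232 to 5467 ± 300.0), NLRC5 (20.8 ± 2.49 to 47.7 ± 0.467) and B2M (6940 ± 617 to 9356 ± 481), the last chosen after its values were seen. NLRC5 loses its call without decitabine replicate 1 (0.148) or 2 (0.137) and with DESeq2 (0.0951), and reads of HLA genes can be shared between paralogs. DNMT1 mRNA, the transcript of the protein that decitabine depletes, was at 15511 ± 159 and 14102 ± 74.0 (log2 fold change −0.14, adjusted p 0.35). Of 18 genes of the DNA methylation machinery only UHRF1 (8089 ± 137 to 10499 ± 354) and ZBTB4 (1551 ± 12 to 2115 ± 128) were called, both higher and both also when adjusted over the list alone. This list had a median of −0.02, a mean of 0.01 and a downward test direction (camera adjusted p 0.928). UHRF1 loses its call without decitabine replicate 1 (0.0933) and ZBTB4 without decitabine replicate 2 (0.077), and both lose theirs in limma without a variance trend (0.106 and 0.0857).

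Among 20 genes of deoxynucleoside analog metabolism in H146, 6 were higher and 4 lower, 6 and 7 when adjusted over the list alone. The list had a median of −0.02, a mean of 0.24 and an upward test direction (camera adjusted p 0.774). Thymidine kinase gene TK1 rose from 6356 ± 593 to 15718 ± 1598 (n = 2 per arm; log2 fold change 1.31) and the nucleoside transporter gene SLC28A1 from 0.513 ± 0.726 to 21.1 ± 0.18 (ratio 41.2, interval 7.09 to 1683). Of 28 chromatin corepressor and Polycomb genes 1 was higher and 5 lower, 1 and 4 when adjusted over the list alone. MTA1 of the NuRD complex fell from 16012 ± 1149 to 11348 ± 1037, and the list median was −0.08 (camera adjusted p 0.217). MTA1 loses its call without decitabine replicate 2 (adjusted p 0.0736) and in limma without a variance trend (0.0954). Of 22 genes of the integrated stress and unfolded protein responses 8 were higher and 3 lower, 8 and 4 when adjusted over the list alone, led by ATF3 (133 ± 0.0217 to 252 ± 25.8). Their median was 0.13 (camera adjusted p 0.158). ATF3 loses its call without decitabine replicate 2 (0.0809). None of the 13 mitochondrially encoded genes was called, over all genes or when adjusted over the list alone (MT-CO1 1089200 ± 46462 and 1242840 ± 207200; median 0.11, camera adjusted p 0.566).

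Beyond the lists, the steepest rises in H146 among protein-coding genes with a mean of at least 50 were VCX, VCX2, VCX3A, BRDT, DAZL and DMRTB1, already given, and a further pair. These are FAM9C, an X-linked testis gene (8.16 ± 5.87 to 1864 ± 26.1; 228-fold), and CALML5, an epidermal calcium-binding protein gene (0.513 ± 0.726 to 309 ± 40.2; ratio 601, interval 109 to 24027). The steepest falls by the same rule were smaller. They are AFM, which encodes afamin (408 ± 45.4 to 95 ± 14.1; 4.30-fold lower), the receptor genes ADRA2A (log2 fold change −1.94) and KISS1R (−1.92), and the amino acid transporter genes SLC38A5 (−1.88) and SLC6A14 (−1.74). The others are the kinase gene MATK (1543 ± 25.8 to 433 ± 77.3; −1.84), the actin-like testis gene ACTL8 (−1.78) and ASCL2 (−1.78). ADRA2A loses its call in limma without a variance trend (adjusted p 0.0793).

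**Figure D1:**
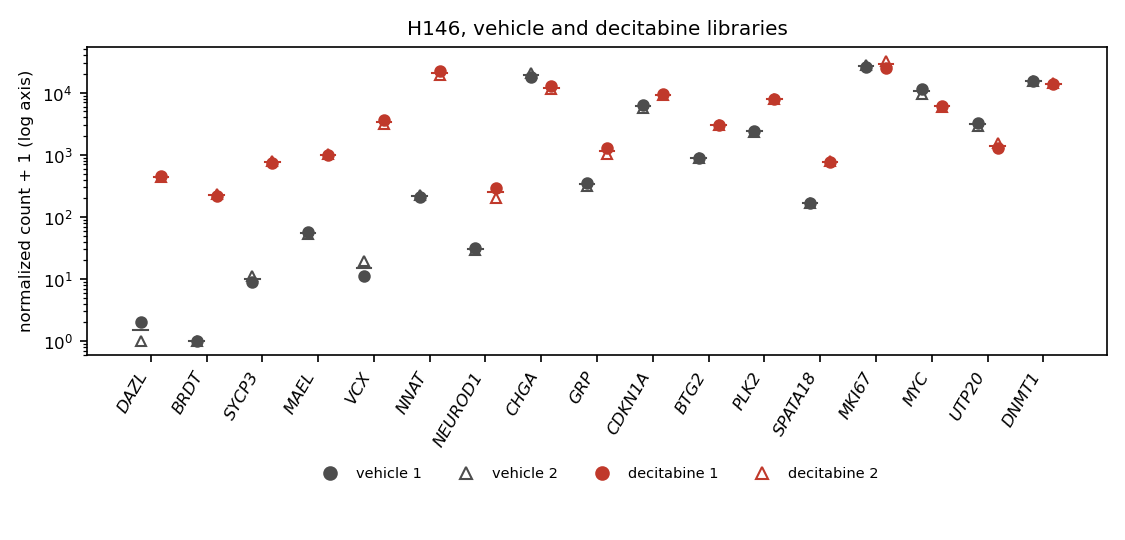
Normalized count plus 1 (log axis) of 17 genes in the 4 H146 libraries, grey for vehicle and red for decitabine, circles for replicate 1 and triangles for replicate 2, with a short line at each mean. DAZL (446 ± 12.9) and NNAT (21121 ± 2176) are far above their vehicle levels, and MYC (6038 ± 114) is below its vehicle level.

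Of 20783 genes tested in H146, 5752 had an adjusted p under 0.05, 3198 higher and 2554 lower after decitabine, and among genes changed 2-fold or more 1388 were higher and 303 lower. The 303 become 483 without vehicle replicate 1, 179 without decitabine replicate 1, 178 without decitabine replicate 2, 193 with DESeq2 and 201 in limma without a variance trend. With the filter of at least 50 the counts are 866 higher and 186 lower. Fewer were called on leaving out a decitabine library, with 2521 genes called without decitabine replicate 1 and 2664 without decitabine replicate 2. Limma without a variance trend called 2164. The authors' deposited table calls 4854 genes in H146, 2676 higher and 2178 lower, and 4740 of them are among the 5752. By fry, which tests whether a set's genes move on balance one way and does not compare them with other genes, 10 of the 22 lists passed, 9 up and 1 down. They include the interferon response (adjusted p 0.0157), immune (0.0157) and neuroendocrine transcription factor (0.0225) lists, which camera did not call, and not the fibroblast list (0.0637). The labels call the replicates duplicates without saying whether they are separate cultures, so the p values measure the spread between these samples only. The strandedness of the libraries is not given in the sources used here, so reads of an overlapping gene on the other strand could be counted.

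In F1339 no gene passed the threshold in limma without a block, and the gene values that follow have no call in that fit. With the replicate number as a block, limma called 1325 genes (777 higher, 548 lower), among them 17 of the 53 named genes. The block assumes that the numbers pair the libraries, which the labels do not state. Germline genes again had the highest list median. Dazl was at 0.540 ± 0.764 in vehicle and 171 ± 194 in decitabine (n = 2 per arm; ratio 317, interval 60.2 to 13360), and Mov10l1, an RNA helicase gene of the piRNA pathway, at 1.57 ± 0.837 and 719 ± 824 (ratio 458, interval 161 to 2291). The F1339 germline genes given here, except Tuba3a and Tuba3b, were chosen after their values were seen. Fkbp6 was at least 88.1-fold, Sohlh2 at least 58.7-fold and Tex11 at least 57.5-fold higher in decitabine, with no reads in vehicle. The decitabine libraries lie far apart, with 34.4 and 308 for Dazl in replicates 1 and 2. The testis tubulin gene Tuba3b was at 158 ± 82.4 and 10810 ± 4923 (68.5-fold) and its near-identical paralog Tuba3a at 221 ± 82.6 and 3872 ± 3817. In contrast to human BRDT, mouse Brdt had reads in vehicle and stood at 596 ± 229 and 576 ± 196. Of 16 tested germline genes 13 had both decitabine libraries above both vehicle libraries and 0 below (1 in 6 is the chance for each direction), and 11 were higher and 0 lower when adjusted over the list alone. The list holds 31 genes, of which 20 have deposited values. As in H146, the filter favours rises among genes near silent in vehicle, so 1 in 6 is not the chance for these. The median log2 fold change was 4.17, also with the 3 genes without vehicle reads at their bound (camera adjusted p 1.9e-13; adjusted p = 0.353 with an estimated correlation).

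Antigen presentation genes were called as a list in F1339, with H2-D1 at 3006 ± 33.7 and 6446 ± 1551 (n = 2 per arm) and the peptide-loading gene Tapbp at 2602 ± 756 and 4435 ± 280.1. H2-K1 (283 ± 78.3 and 708 ± 345) and B2m (617 ± 103 and 1017 ± 30.9) were chosen after their values were seen, and reads of H2 genes can be shared between paralogs. Of 17 members 9 were above and 0 below in full separation, and 0 were called when adjusted over the list alone. The median was 1.08 (camera adjusted p 2.6e-07; adjusted p = 0.353 with an estimated correlation). Of 24 interferon response genes 13 were above and 2 below, and 0 when adjusted over the list alone. The interferon list had a median of 0.45 (camera adjusted p 0.0010; adjusted p = 0.353 with an estimated correlation), and its call ends without vehicle replicate 2 (0.055). Usp18 was at 73.6 ± 8.91 and 156 ± 44.1, chosen after its values were seen, and the abundant member Cmpk2 at 2080 ± 180.4 and 1756 ± 19.4.

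Genes of the non-neuroendocrine state and the Notch pathway in F1339 had a median of 0.58 over 22 members, 5 above and 0 below in full separation, 4 higher and 0 lower when adjusted over the list alone (camera adjusted p 1.6e-05; adjusted p = 0.353 with an estimated correlation). Rest, the repressor of neuronal genes, was at 27.4 ± 8.18 and 142 ± 48.4 (n = 2 per arm), Tgfbr2 at 6.06 ± 2.46 and 39.9 ± 8.92, and Anxa1 at 5.57 ± 1.77 and 43.8 ± 14.5, all chosen after their values were seen. Hey1, a Notch effector gene, stood at 2114 ± 488 and 3158 ± 395, and Yap1 at 103 ± 48.4 and 202 ± 103. With the replicate block both Hey1 and Yap1 were called higher (limma adjusted p 0.0101 and 0.0366). Of 14 neuroendocrine transcription factors 1 was above and 5 below, and 0 when adjusted over the list alone. The list, with a median of −0.18, was called lower (camera adjusted p 0.0256; adjusted p = 0.367 with an estimated correlation), a call that ends without vehicle replicate 1 (0.499). Insm1 was at 44282 ± 17608 and 31933 ± 10730, and Neurod1 at 237 ± 31.5 and 280.2 ± 63.9, each with overlapping arms. Within each library number Insm1 was lower in decitabine (56733 to 39520, and 31831 to 24346). With the replicate block Insm1 was called lower (limma adjusted p 0.0311). The 36 effector genes were not called, over all genes or when adjusted over the list alone (median −0.06, or 0.04 with libraries rescaled to the same total; camera adjusted p 0.221), with Chga at 70496 ± 12202 and 71140 ± 11596. The 6 tuft cell genes had a median of 0.91 with 1 above and 0 below and 0 when adjusted over the list alone (camera adjusted p 0.0410; adjusted p = 0.367 with an estimated correlation). That call ends without vehicle replicate 2 (0.113), without decitabine replicate 2 (0.171) and with libraries rescaled to the same total (0.11). Pou2f3, a tuft cell factor gene, had 11.5 ± 7.15 and 28.0 ± 24.3.

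Markers of other cell types were higher as lists in F1339 as in H146. Of 11 endothelial and lung epithelial markers 5 were above and 0 below, and 2 higher when adjusted over the list alone. Their median was 1.25 (camera adjusted p 1.4e-05; adjusted p = 0.353 with an estimated correlation). The surfactant gene Sftpb, chosen after its values were seen, was at 4.49 ± 3.30 and 39.2 ± 13.8 (n = 2 per arm), while the abundant Sftpc was at 3199 ± 463 and 3298 ± 395. Of 9 fibroblast markers 4 were above and 0 below, and 0 when adjusted over the list alone. The fibroblast median was 0.84 (camera adjusted p 0.0165; adjusted p = 0.353 with an estimated correlation), and Fn1 was at 5272 ± 4.50 and 5865 ± 11.4. The immune and the X-linked cancer-testis lists, of 18 and 30 members, had 3 tested members each in F1339, too few for a test. When adjusted over the list alone, 2 of the cancer-testis members were higher, Xlr3c (9.86 ± 10.9 and 155 ± 137) and Xlr3a (19.4 ± 15.3 and 123 ± 88.6). None of the 3 immune members was, and of these Cd79a was at 76.6 ± 62.8 and 143 ± 19.6.

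Proliferation genes were lower as a list in F1339, with a median of −0.20 over 35 members, 1 above and 9 below and 0 when adjusted over the list alone (camera adjusted p 0.00024; adjusted p = 0.367 with an estimated correlation). The call ends without vehicle replicate 2 (0.071) and without decitabine replicate 1 (0.419). Top2a was at 81507 ± 6775 and 69733 ± 14179 (n = 2 per arm), but Mki67 at 38031 ± 6495 and 44397 ± 19064. Genes of deoxynucleoside analog metabolism were lower too, with a median of −0.27 over 19 members, 1 above and 8 below and 0 when adjusted over the list alone (camera adjusted p 0.0055; adjusted p = 0.367 with an estimated correlation), a call that ends without vehicle replicate 2 (0.222) and without decitabine replicate 1 (0.069). The ribonucleotide reductase gene Rrm1 was at 28299 ± 3774 and 21744 ± 1726. Rrm1, Rrm2 and Tyms are on the proliferation list as well, so the results of these lists are not independent. Tk1, which rose in H146 and was chosen here after its values were seen, was at 8138 ± 2895 and 5333 ± 664. Of 26 p53 targets 7 were above and 5 below, and 0 when adjusted over the list alone. The median was 0.08 (camera adjusted p 0.0410; adjusted p = 0.391 with an estimated correlation), and the p53 call ends without vehicle replicate 1 (0.222) and without decitabine replicate 2 (0.207). Cdkn1a was at 1040 ± 694 and 3573 ± 2534, while Btg2, whose human counterpart was called higher in H146, was at 7074 ± 1605 and 4749 ± 97.5. With the replicate block both were called, Cdkn1a higher (limma adjusted p 3.6e-05) and Btg2 lower (0.0216). The 21 cell cycle exit genes were not called, over all genes or when adjusted over the list alone (camera adjusted p 0.354), with Cdkn1b at 10162 ± 734 and 10498 ± 987.

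The MYC list was called lower in F1339 over 30 members, 2 above and 7 below and 0 when adjusted over the list alone. Its median was −0.07, or 0.03 with libraries rescaled to the same total (camera adjusted p 0.0414; adjusted p = 0.442 with an estimated correlation). The call ends with that rescaling (0.189), without vehicle replicate 2 (0.736) and without decitabine replicate 2 (0.207). Myc itself, of low abundance, was at 51.1 ± 32.6 and 179 ± 83.5 (n = 2 per arm), opposite to MYC in H146, and the abundant paralog Mycl was at 315116 ± 110154 and 235596 ± 87099. Mycn was at 622 ± 338 and 660.2 ± 255. Rb1 stood at 5061 ± 431 and 3407 ± 35.6 with the arms separated, and was called lower with the replicate block (limma adjusted p 0.0085). Of 17 imprinted genes 4 were above and 0 below, and 0 when adjusted over the list alone. The imprinted median was 0.24 (camera adjusted p 0.0187; adjusted p = 0.367 with an estimated correlation), a call that ends without vehicle replicate 2 (0.123) and without decitabine replicate 1 (0.053). Nnat, which rose 97.7-fold in H146, was already at 31722 ± 8798 in F1339 vehicle cells and at 37221 ± 9476 in decitabine.

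The other F1339 lists were not called, and none of their genes was called over all genes or when adjusted over the list alone. Dnmt1 mRNA was at 49022 ± 1032 and 45687 ± 1269 (n = 2 per arm), and the 18 DNA methylation genes had a median of −0.04, a mean of 0.00 and a downward test direction (camera adjusted p 0.724; median 0.05 with libraries rescaled to the same total). The 26 apoptosis regulators, among them Cycs at 13183 ± 3738 and 13101 ± 2986, had a median of −0.01, a mean of 0.06 and a downward test direction (camera adjusted p 0.726; median 0.09 with that rescaling). The 28 chromatin genes, Chd4 at 75589 ± 2305 and 77248 ± 7151 among them, had a median of −0.05 (camera adjusted p 0.169; 0.04 with that rescaling). The 22 stress response genes, among them Hspa5 at 29259 ± 7378 and 34022 ± 3496, had a camera adjusted p of 0.0534, and are called without decitabine replicate 2 (0.0039). The 13 mitochondrially encoded genes, mt-Co1 at 412242 ± 163885 and 387597 ± 91762 among them, had a median of −0.02, a mean of 0.07 and a downward test direction (camera adjusted p 0.907; median 0.07 with that rescaling).

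**Figure D2:**
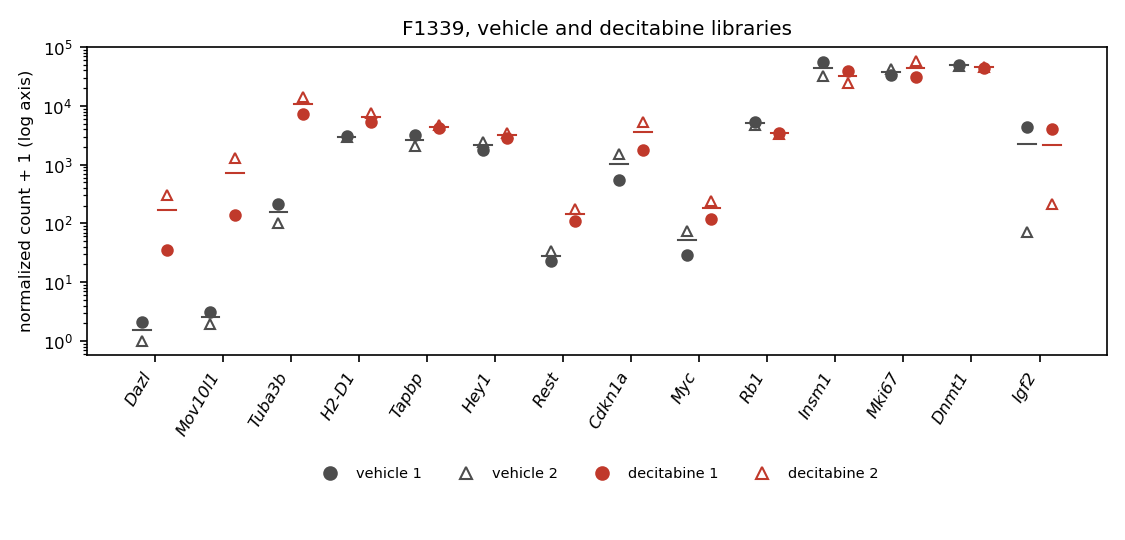
Normalized count plus 1 (log axis) of 14 genes in the 4 F1339 libraries, grey for vehicle and red for decitabine, circles for replicate 1 and triangles for replicate 2, with a short line at each mean. Dazl (171 ± 194) and Tuba3b (10810 ± 4923) are above their vehicle levels, with the decitabine libraries far apart.

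In F1339 limma called 0 of 16680 genes, with 932 at an unadjusted p under 0.05, and edgeR called 0, with 931. With the replicate block limma called 1325, edgeR 1453 and DESeq2 865. Without the block DESeq2 called 107, 77 higher and 30 lower, and the authors' deposited table also calls 107 genes. These are the same 107 genes, called by DESeq2 on the same counts, so the deposited calls are not a second result. DESeq2 called 25 unchanged genes in the F1339 simulation, which left out any spread shared by libraries of the same number. The simulation therefore cannot tell what share of the 107 is false. In the authors' deposited table the adjusted p is 9.6e-35 for Tuba3b (68.6-fold), 6.3e-09 for Mov10l1 (464-fold), 9.5e-07 for Tex19.1 (175-fold) and 5.7e-04 for Fkbp6, and 0.0033 for H2-D1 (2.14-fold). It also calls higher the epithelial factor gene Klf4 (5.14-fold, adjusted p 0.0036) and Rest (5.19-fold, 0.026), all genes from the authors' deposited table chosen after their values were seen. Of these 107 genes 8 are members of the germline list. Replicates differed more in F1339, with a median SD of log2 values of 0.211 in vehicle and 0.185 in decitabine against 0.116 and 0.107 in H146. Part of the F1339 spread is shared by libraries of the same number, whose deviations from the arm mean correlate across genes at 0.685. By fry 0 of the 20 lists tested passed in F1339, and the F1339 p values, like those of H146, measure the spread between these samples only.

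**Figure D3:**
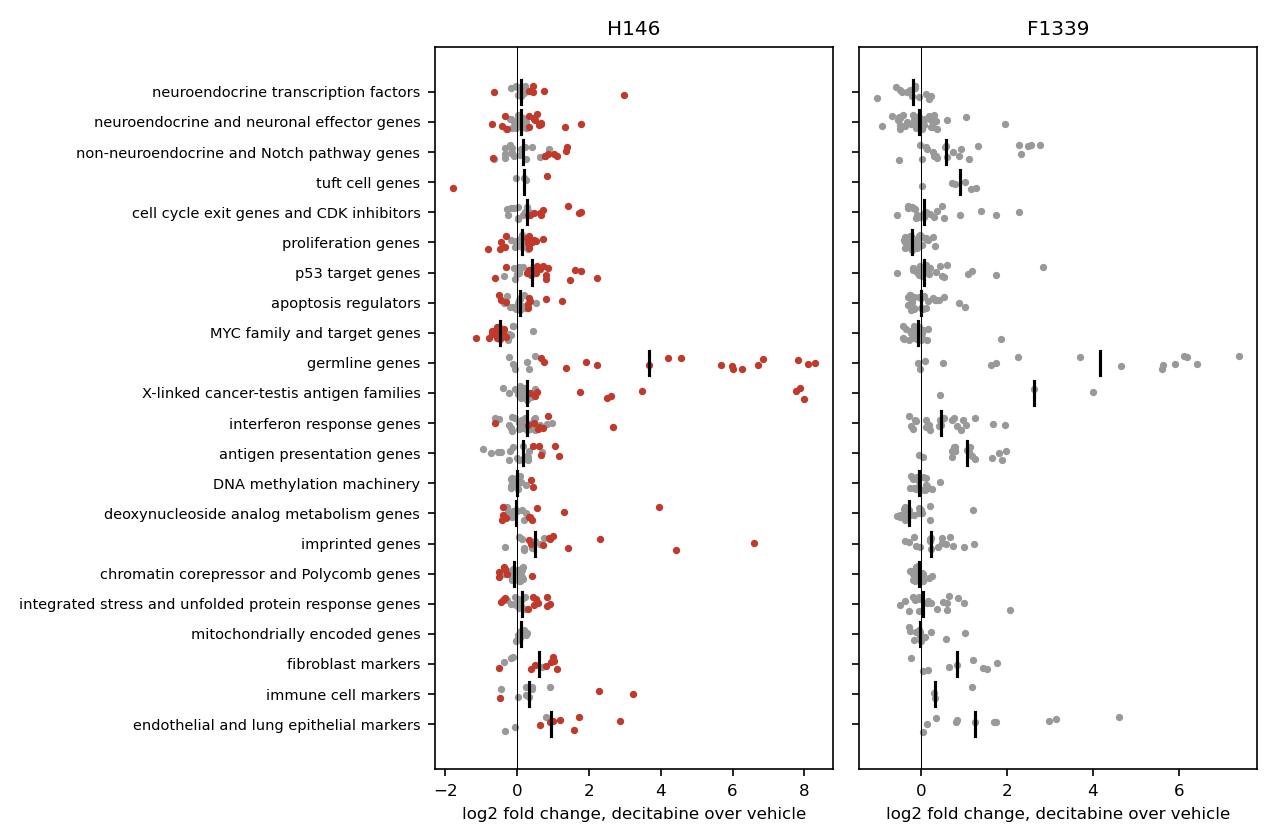
Log2 fold change, decitabine over vehicle, of each tested member of the 22 lists in both lines, red where called over all genes, with a black bar at the list median. The germline list has the highest median in H146 (3.66) and in F1339 (4.17).

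Of 11 germline genes tested in both lines, 8 had higher values after decitabine in each. MOV10L1, FKBP6, DAZL, TEX11, SOHLH2, TEX14, TEX101 and PIWIL2 had both decitabine libraries above both vehicle libraries in each line. This set was named after the values were seen, and the filter favours rises among genes near silent in vehicle. In H146 the log2 fold changes of TEX101 (0.28), TEX11 (0.50) and FKBP6 (0.66) were small, and those of the others were 1.36 to 8.30. TDRD1 and BRDT rose in H146 and did not separate in F1339. Of 11826 genes with a one-to-one symbol tested in both lines, 1777 were higher and 1751 lower in H146 by limma, 0 in F1339, and so 0 in both (0 expected by chance). With the replicate block in each line, 201 genes were higher in both against 80.4 expected and 104 lower in both against 62.7. In opposite directions there were 53 and 53. With DESeq2 in each line, a test chosen after the result was seen, 22 genes were higher in both against 6.75 expected (hypergeometric exact p 1.3e-07) and 8 lower in both against 3.89 (exact p 0.033), with 1 and 1 in opposite directions. No difference between the lines was tested. Across genes, which are not independent of one another, the log2 fold changes of the lines had a Pearson r of 0.234 and a Spearman rho of 0.171. The genes higher by 2-fold or more in H146 were also tested as a list in F1339, again chosen after the result was seen. The 448 of them tested there had a median of 0.35, and 33.3% had both decitabine libraries above both vehicle libraries against 17.9% of all genes (camera p 3.6e-09; p = 0.069 with an estimated correlation). Without the germline, cancer-testis and imprinted genes, 439 genes gave 32.8% (camera p 1.2e-08; p = 0.068 with an estimated correlation). The 64 genes lower by 2-fold or more in H146 gave no call in F1339 (camera p 0.32). Their test direction there was upward too, opposite to H146, with a median of 0.17. Of these 64 genes 18.75% had both decitabine libraries above both vehicle libraries, against 17.9% of all genes, and 7.81% had both below.

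**Figure D4:**
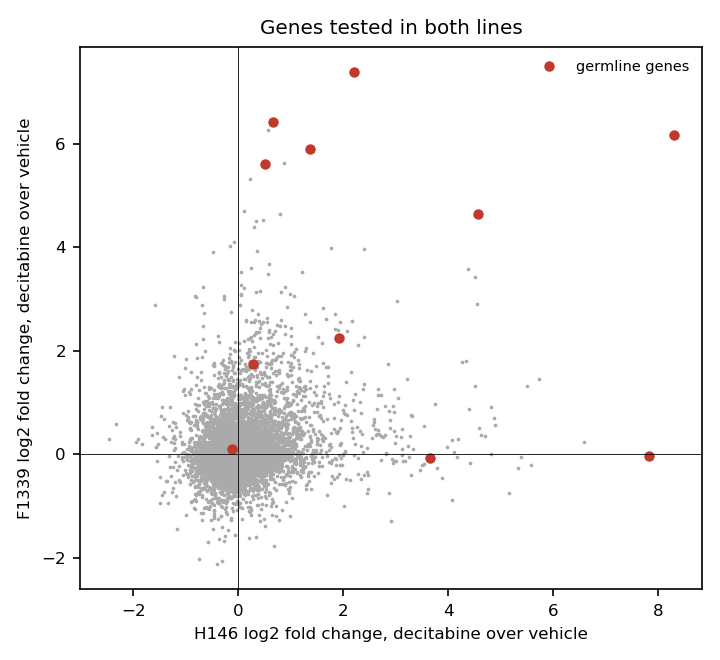
Log2 fold change after decitabine in H146 (x axis) against F1339 (y axis), 1 point per gene tested in both lines, germline genes in red. Of 11 germline genes 8 are separated and above 0 on both axes, TDRD1, BRDT and TEX15 are not, and over all points the Pearson r is 0.234.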

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

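The tests of library scaling and of reads from MYC paralogs were set out before their results were seen.

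MYC moved apart in the 2 lines: in H146 both decitabine libraries are below both vehicle libraries (log2 fold change −0.79), and in F1339 both are above (1.86). This opposite separation is what singled it out, and the difference between the lines was not tested. Chance gives opposite full separation in 5.56% of comparisons, or 1.94 of the 35 genes and lists compared, and 1 was found, so the count is not above chance. The decrease in H146 was called by limma (adjusted p 2.2e-06), while the F1339 value was not (0.89).

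With libraries rescaled to the same total the values are 1.96 in F1339 and −0.79 in H146, of unchanged sign. That rescaling moves the median log2 fold change of all F1339 genes only from −0.01 to 0.09, so it could hardly have turned the sign. Only the choice between these scalings is argued against as the source. Reads of a paralog counted for Myc in F1339 are argued against too, since the higher of the changes of Mycl and Mycn there is 0.15, far under that of Myc. The F1339 value is 2.55 without vehicle replicate 2 and 1.18 without vehicle replicate 1, and with the replicate block, which assumes that the numbers pair the libraries, F1339 Myc is called (adjusted p 0.0036). A difference between the lines, which the design names (species, 96 h against 72 h), stays open and was not tested.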

How the results depend on the processing

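Chosen after the data were seen were DESeq2 and left-out libraries for the overlap of the lines, and edgeR and DESeq2 with a replicate block. Unless a cause is named here, the cause was not tested.

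In H146, where limma called 5752 genes, the other pseudocounts, filters and rescalings, edgeR and DESeq2 gave 4857 to 6083, with 52.0% to 59.4% of them higher. eBayes without a variance trend gave 2164 (1581 higher, 583 lower). Leaving out 1 library gave 2521 (without decitabine replicate 1) to 5552, with 2664 without decitabine replicate 2. In F1339 limma called 0 genes under each pseudocount, filter and rescaling, without a trend, in edgeR and with each library left out (0 to 0), and DESeq2 called 107.

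Of the lists, 8 were called in H146 and 13 in F1339 with the preset correlation, 0 and 0 with an estimated one, and fry called 10 and 0. Leaving out 1 library gave 7 to 9 lists in H146 and 7 (without vehicle replicate 2) to 11 in F1339. With libraries rescaled to the same total, 11 were called in each line, in H146 also the neuroendocrine effector (0.0406), proliferation (0.0309) and interferon (0.0481) lists. Of 71 named genes called in H146, 42 kept their call under all alternatives run, 29 lost it under at least 1, and 0 were called in the other direction. In F1339, of 53 named genes, 17 were called under at least 1 alternative, all of them with the replicate block (Myc among them) and H2-D1, Tuba3a and Tuba3b also with DESeq2. The F1339 sign of 22 uncalled named genes turned under at least 1 alternative.

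The labels give vehicle and decitabine libraries the same numbers without stating that these are paired. With the number as a replicate block, 5192 genes were called in H146 and 1325 in F1339 (777 higher, 548 lower). The block called 11 lists in H146, with the neuroendocrine effector, non-neuroendocrine and interferon lists at 0.0499, and 13 in F1339, where the MYC list lost its call (0.064) and the stress response list gained one (0.0456). RB1 in H146 lost its call with the block (0.0546). The block removes a difference that F1339 libraries of the same number share: their deviations from the arm mean correlate across genes, which are not independent, at 0.685, against −0.03 in H146. edgeR and DESeq2 with the block called 1453 and 865 in F1339 and 4979 and 3077 in H146. Genes called in the same direction in both lines were 0 by limma, 305 with the block (201 higher against 80.4 expected, 104 lower against 62.7; 53 and 53 opposite), and 30 with DESeq2, with 0 to 0 on leaving out 1 library in both lines.

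Depth limits genes with few reads, and the spread between libraries limits F1339 more: a 2-fold change was called in 20.9% of simulated F1339 genes and in 85.1% of H146 ones. Rescaling to the same total moves the median log2 fold change of all F1339 genes from −0.01 to 0.09.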

Other observations

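The tests of exchanged H146 columns and of F1339 depth were chosen after the result was seen, as were the genes given in the next paragraph.

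H146 had further large changes outside the lists. GSTP1, a detoxification gene often methylated in cancers, rose from 117 ± 3.11 to 3497 ± 174 (29.8-fold, n = 2 per arm), the syncytin gene ERVW-1 from 3.53 ± 2.09 to 492 ± 62 (139-fold), and CTCFL, a germ cell paralog of CTCF, from 16.8 ± 2.43 to 1015 ± 60.7. KRT7 rose from 73.6 ± 4.79 to 1254 ± 4.19, PLIN2 from 34.6 ± 7.74 to 1676 ± 31.8, and the developmental factor gene HOXA9 from 58 ± 16.7 to 464 ± 3.67. Among genes that fell were HIST1H1C, from 1301 ± 52 to 442 ± 12.2, the transferrin receptor gene TFRC, from 14092 ± 2912 to 6706 ± 1032, and CD82, from 5363 ± 324 to 1808 ± 125. Of 1476 lincRNAs tested 203 (13.8%) were higher by 2-fold or more, against 940 of 15242 protein-coding genes (6.17%). Of the same genes 60 lincRNAs and 127 protein-coding genes were lower by 2-fold or more. As a share of the genes tested, lincRNAs thus exceeded protein-coding genes among the falls as well, and the excess is not particular to rises.

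Genes higher by 2-fold or more in H146 were more often near silent before treatment: 37.3% of the 1388 had a mean under 10 in vehicle, against 12.5% of the 303 lower genes with a mean under 10 in decitabine (Fisher's exact p 6.2e-19). This is consistent with decitabine releasing silenced genes, though a low starting level also makes a large fold easier to reach. An X-chromosome excess was not shown, with an odds ratio of 1.24 (Fisher's exact p 0.074) and 1.11 without the germline and cancer-testis lists (p 0.25). Among protein-coding genes alone the ratio was 1.49 (p 0.0071), and 1.32 without those lists (p 0.054). Neighbouring genes were both higher in 58 pairs, at and not above the 95th percentile of shuffles (58). Zinc finger genes were not called as a group in H146 (p = 0.58 with an estimated correlation, 0.071 with the preset one) or in F1339 (0.483 and 0.052).

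The authors' deposited fold changes in H146 run from decitabine to vehicle, which raises the question whether the columns were exchanged. That is argued against by the germline genes, which are higher after decitabine as a list in F1339: 20 of the 23 tested are higher in both H146 libraries titled decitabine than in both titled vehicle. The F1339 list call is lost with an estimated correlation (adjusted p = 0.353) and by fry (0.291), while 13 of its 16 members had both decitabine libraries above both vehicle libraries. Why the sign differs between the deposited tables stays open.

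F1339 libraries numbered 1 and 2 differ in both arms, and the design has no group for the numbers, so no biological difference that the labels name was tested. Of 13551 genes, 8 were at least 10-fold lower and 25 at least 10-fold higher in number 2 than in number 1 of both arms, against 0 and 0 of 15815 in H146. Depth is argued against, with a ratio of library 2 to 1 of 1.002 in decitabine (1.11 in vehicle), since depth would have to differ in both arms. Cells of another type in the libraries numbered 2 are argued against for the 8 lower genes, which would need most RNA to come from such cells, since the neuroendocrine effector genes have a median difference of −0.18 in vehicle and −0.06 in decitabine. For the 25 higher genes a smaller share of other cells stays open.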
